A study of Arabidopsis thaliana and Arabidopsis lyrata with 4 samples.

How the data were processed

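Uncapped, polyadenylated RNA from inflorescences was sequenced from its 5' end in 4 libraries, 2 of *Arabidopsis thaliana* (accession Col-0) and 2 of *Arabidopsis lyrata* (subspecies *lyrata*). Per the labels' protocols, polyA+ RNA was ligated to a 5' adapter without prior fragmentation, so that only RNAs carrying a 5' monophosphate received the adapter, and the libraries were read on a SOLiD instrument from that adapter. By this protocol each tag begins at the 5' end of an RNA that took the adapter, whether a decay or cleavage intermediate or another uncapped RNA such as ribosomal RNA. The labels' protocols also state that *A. lyrata* received a cold period before flowering and that *A. thaliana* did not. The series describes the 2 libraries of a species as biological replicates.

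For every library the authors deposited the alignments of tags to transcript models and a table of tag counts per transcript position. The deposited tables give, for each position, the count of all alignments, a count in which a tag with several alignments is divided among them, the count of tags with a single alignment, and a category number. The alignment score deposited by the authors was used only as the files give it, and no filter on it was added. All alignments lay on the forward strand of the models, and the summed count of each table equalled the number of lines of its alignment file. The aligner's version, the source of the *A. thaliana* models and the filters behind the alignments are not given in the sources used here. The category number was not used here.

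The divided count was the main measure, and the count of tags with a single alignment was an alternative named beforehand. The choice of the divided count was made after the files had been read. Tags carry no molecular identifiers, so intervals cover counting error only.

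The plan fixed before the data were examined named a negative binomial quasi-likelihood test. The deposited tables are sectioned by transcript, and under the rules used here such columns do not qualify for a count model, so voom and limma version 3.58.1 in R version 4.3.3 took its place. Genes were paired through the *A. thaliana* locus that the *A. lyrata* model name carries. Of 26590 *A. lyrata* models with tags, 11442 carried such a name, for 11205 distinct loci. The 210 loci with more than 1 *A. lyrata* model were left out, and 10635 pairs had tags in *A. thaliana*. A gene was kept when at least 2 libraries reached the equivalent of 10 counts at the median library size and its total was at least 15, which left 9428 genes. Factors from trimmed means of log ratios scaled the libraries, and p-values were adjusted by the Benjamini-Hochberg method at a false discovery rate of 0.05. CPM of genes refer to the scaled total of the genes tested, and CPM at single positions to all tags of the library. On simulated counts for these genes, 91.9% of the 4-fold changes (91 of 99 genes) and 22.2% of the 2-fold changes (22 of 99 genes) were recovered, with 10 false calls among 9251 genes.

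The 17 gene lists were fixed before the data were examined and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. On simulated counts the 1 raised list was called and 0 of 10 random lists were. The simulated genes varied independently, so this does not cover false calls in lists whose members vary together. The estimated correlation was 0.16 for photosynthesis and 0.41 for the tapetum and pollen wall. The genes named in the text followed a rule fixed beforehand. Among genes past the threshold whose libraries did not overlap between species and whose mean log2 CPM exceeded the median of 5.08, the 10 largest rises and the 10 largest falls were taken, with up to 4 members of each list by smallest p. The result of 1 gene that this rule names is not reported here. For cleavage sites the rule took the 15 pairs with the most tags at the site among those with a peak in both replicates, pairs past the threshold in the difference of shares, and pairs with a peak in 1 species only. It could be applied to the placed sites of *A. thaliana* alone, and the *A. lyrata* targets and further *A. thaliana* targets named from their highest positions were chosen after their values were seen.

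Cleavage sites were sought for 154 listed pairs of a small RNA and a target, by complementarity to the first transcript model in the TAIR10.1 reference annotation (mismatch 1, G:U pair 0.5, doubled at small RNA bases 2 to 13), with a penalty of at most 4.5, which 131 pairs met. The authors' models often begin at another base than the reference models. Each was therefore placed from the bases at which alignments differed from the authors' model, since a base recorded as different cannot equal the model's own base at the right offset. Offsets of up to 700 nt were weighed for models with at least 8 differing bases, and a posterior of 0.95 was required. Of 9053 models with enough differing bases, 4012 were placed, 2655 of them at offset 0. On simulated differing bases, 96.8% of placed models had the true offset (241 of 249). The placement was devised after the data had been examined. A site counted as having a peak when the highest position of the transcript, with at least 2 tags, lay within 1 nt of it, ties allowed, and 10000 draws of a random covered position per pair gave the permutation p. With sites set at random positions, 5% of 200 sets reached a p of 0.05.

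Transcript sequences of *A. lyrata* were not used here, so its cleavage sites could not be placed by sequence. In their place the position with the most tags was taken where it was the same, within 1 nt, in both replicates of a listed target with at least 20 tags in each. The share of tags at that position was compared between species with limma on the tags at the position and elsewhere, with a term per library and a species by position interaction, for targets with at least 10 tags at the position. On simulated shares, 100 of 100 changes of 3-fold in the odds were recovered with 3 false calls among 100 unchanged targets, a number of targets far above the 11 real ones. The use of highest positions for this test was chosen after the data had been examined. Profiles along transcripts used placed *A. thaliana* models with a coding sequence, and intervals came from 1000 bootstrap resamples of transcripts.

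Alternatives were other scaling, no filter, tags with a single alignment, leaving out the highest position, a replicate block, leaving out each library, and other windows, penalties and count minimums. Added after the data had been examined were distinct positions in place of tags, every alignment counted once, pairs whose last covered positions differ by under 10%, limma-trend, and a posterior of 0.9. Figures and tables were made with Python version 3.11.15, numpy version 2.4.6, scipy version 1.17.1, pandas version 2.3.3 and matplotlib version 3.10.9.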

Results

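Degradome libraries of inflorescences were compared between *A. thaliana* (n = 2) and *A. lyrata* (n = 2), which record where uncapped RNAs begin on each transcript model. The *A. thaliana* libraries held 9031213 and 9612258 tags on 25490 and 26763 transcript models, of which 3748204 and 3377660 had a single alignment. The *A. lyrata* libraries held 7087227 and 15665420 tags on 24331 and 24810 models, of which 4557766 and 8587134 had a single alignment. Ribosomal RNA took 38.6% and 48.7% of the *A. thaliana* tags and transcripts of the organelle genomes took 20.5% and 17.2%, while protein-coding transcripts of the nuclear genome took 29.2% and 24.1%. The pairs of orthologous genes carried 19.4% and 15.9% of the tags in *A. thaliana* and 26.7% and 25.5% in *A. lyrata*. P-values and SE of the comparison per gene refer to these libraries only. They rest mostly on a spread pooled over genes, with 192 prior and 2 residual degrees of freedom. A gene's own difference between replicates therefore counts for little in them. The permutation and Fisher p-values do not measure the spread between libraries.

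The first comparison asked which genes differed between the species in the abundance of uncapped 5' ends. Total or capped RNA is not among the samples, so a difference in transcript level cannot be told apart from one in decay or cleavage. GRP19, a glycine-rich protein of the pollen coat, stood at 613 ± 220 CPM in *A. thaliana* and 5932 ± 1642 CPM in *A. lyrata* (SD, n = 2). CAB1, a chlorophyll-binding antenna protein, stood at 6308 ± 58.4 and 1149 ± 60.5 CPM (SD, n = 2). The log2 fold of GRP19 was 3.25, and 1.17 with distinct positions in place of tags, and that of CAB1 was -2.46, and -3.69 with tags of a single alignment. Of 9428 genes tested with limma, 2441 passed a false discovery rate of 0.05, with 1005 higher and 1436 lower in *A. lyrata*. The count was 1257 without *A. thaliana* replicate 1 and 1373 without *A. thaliana* replicate 2, and without *A. lyrata* replicate 2 it was 1049 higher and 950 lower. The libraries of the species did not overlap for 6041 genes, where a random order gives 33.3% of genes.

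Among genes whose mean over both species exceeded the median, AT5G35753, AT2G41415 and AT4G03410 rose most, by 7.48 ± 1.203, 6.62 ± 0.96 and 5.33 ± 0.43 (log2 fold ± SE). In *A. thaliana* AT5G35753 had only 5 and 6 tags and AT2G41415 had 13 and 6, so the size of their folds rests on few tags. AT5G35753 was not among the genes tested with distinct positions in place of tags or without either *A. lyrata* replicate, so its rise was not checked there. PRIN2, a factor of plastid transcription, rose by 3.98 ± 0.21, from 139 to 2192 mean CPM, and LCR66, a small cysteine-rich protein, by 4.43 ± 0.82. MEE48, AT3G57320, AT1G30020 and AT5G16920 rose by 4.08, 3.90, 3.83 and 3.82 on the log2 scale. AT5G13380 rose by 3.82, but its log2 fold was -5.51 with tags of a single alignment and -3.80 with distinct positions. Among the largest falls, GILT had a log2 fold of -7.25, from 505 ± 50.9 to 2.89 ± 1.90 CPM (SD, n = 2). SNG1, the sinapoyltransferase that makes sinapoylmalate, fell by 5.95 ± 0.77 on the log2 scale, and GolS1, a galactinol synthase, fell by 4.59 ± 0.50. LEA7, a late embryogenesis abundant protein, fell by 5.60 ± 0.81 and the cell wall enzyme XTH19 fell by 4.15 ± 0.49. In *A. lyrata* GILT had only 3 and 17 tags, SNG1 5 and 27, and LEA7 2 and 52, so the size of their folds rests on few tags too. The log2 folds of AT4G23680, AT1G05340, AT1G11850 and AT3G56880 were -6.44, -4.74, -4.56 and -4.14, and that of the antenna protein LHCB2.3 was -4.24. Values that moved by over 1.5 times in fold follow, all on the log2 scale. With distinct positions in place of tags, AT1G11850 was at -0.85, PRIN2 at 1.74, AT4G03410 at 2.26 and AT3G57320 at 1.91. AT2G41415, AT1G30020 and AT5G16920 were then at 4.87, 2.95 and 3.07, and AT4G23680, AT1G05340 and GolS1 at -5.29, -4.14 and -3.85. With the highest position of each transcript left out, AT1G11850 was at -1.43, AT5G35753 at 5.62, AT2G41415 at 7.28 and LCR66 at 5.08. GILT, SNG1, LEA7, AT1G05340 and XTH19 were then at -9.43, -6.63, -6.68, -5.36 and -5.52. With tags of a single alignment, AT5G35753, AT4G03410, GILT, SNG1 and LHCB2.3 were at 6.10, 6.19, -8.70, -6.78 and -5.12, and with every alignment counted once AT5G35753, AT4G03410 and AT5G13380 were at 8.60, 3.96 and 4.81. LCR66 was at 5.83 without *A. thaliana* replicate 1 and 3.18 without replicate 2, AT3G57320 at 3.00 and 4.60, and AT1G30020 at 4.54 and 3.20. LEA7 was at -4.59 without *A. lyrata* replicate 1 and -7.92 without replicate 2, and AT4G03410 at 6.11 and 4.40. Without *A. lyrata* replicate 2, MEE48, AT1G30020, GILT, AT4G23680, SNG1 and AT1G05340 were at 4.72, 4.59, -8.09, -7.18, -6.82 and -5.70. With the replicate block LCR66 and LEA7 were at 3.78 and -4.89, and with limma-trend LEA7 was at -6.30.

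Among the 17 gene lists, 4 passed an adjusted p of 0.05 with camera at the preset correlation. Of 25 measured photosynthesis transcripts, 23 fell and 0 rose (adjusted p = 6.64e-40), with a median log2 fold of -1.40. The adjusted p was 0.355 with an estimated correlation, and the median was -0.76 with distinct positions in place of tags. RBCS3B, a small subunit of Rubisco, fell by 2.06 ± 0.13 on the log2 scale, RCA, the Rubisco activase, fell by 2.15 ± 0.14 and LHCA4, an antenna protein of photosystem I, fell by 2.28 ± 0.17. With distinct positions RBCS3B was at -0.41 and RCA at -0.81. Of 11 measured transcripts of the tapetum and pollen wall, 10 rose and 0 fell (adjusted p = 1.45e-11), with a median log2 fold of 3.25. The adjusted p was 0.608 with an estimated correlation, and the median was 2.64 without *A. lyrata* replicate 1. AMS, a transcription factor of the tapetum, rose by 3.499 ± 0.48, LAP6, a polyketide synthase of sporopollenin formation, by 3.43 ± 0.45 and DRL1 by 2.24 ± 0.36. AMS was at 4.25 without *A. thaliana* replicate 1 and 2.78 without replicate 2. Of 10 heat response transcripts, 4 fell and 0 rose (adjusted p = 0.0298), with a median log2 fold of -2.17. The adjusted p was 0.608 with an estimated correlation. The log2 folds were -3.16 ± 0.61 and -1.96 ± 0.41 for the chaperones HSP90.1 and HSP101, -2.37 ± 0.80 for the heat shock factor HSFA2 and -6.62 ± 1.63 for the coactivator MBF1C. In *A. lyrata* MBF1C had only 5 and 1 tags, HSFA2 6 and 28, and HSP90.1 6 and 63. Adjusted over the list alone, 5 heat response transcripts fell. Without *A. thaliana* replicate 2 the heat response list had an adjusted p of 0.194 with camera in limma and a median of -1.37, and HSP101 at -1.27 and HSFA2 at -1.70 did not pass. HSFA2 also did not pass without *A. lyrata* replicate 2, at -3.11. Without *A. thaliana* replicate 1, HSP90.1, HSP101 and HSFA2 were at -3.97, -2.80 and -3.45. HSP90.1 was at -2.49 without *A. lyrata* replicate 1 and -4.72 without replicate 2, and MBF1C at -7.72 and -4.79. With distinct positions MBF1C was at -4.26 and HSFA2 at -3.35, and with the highest position left out they were at -7.55 and -5.97. Of 10 transcripts of floral organ identity and the meristem, 5 rose and 1 fell (adjusted p = 0.0363). The adjusted p was 0.608 with an estimated correlation. AP1 and SEP3, floral MADS-box factors, rose by 1.96 ± 0.21 and 1.15 ± 0.24, CRC, a carpel factor, rose by 1.92 ± 0.33, and STK, an ovule factor, fell by 2.35 ± 0.46 on the log2 scale. AP1 was at 1.26 with distinct positions and STK at -1.36 without *A. lyrata* replicate 2. The floral list lost its call without *A. thaliana* replicate 1 (adjusted p = 0.0609), *A. thaliana* replicate 2 (0.113) or *A. lyrata* replicate 2 (0.0853), and with distinct positions in place of tags (0.299). With fry, the adjusted p of a change on balance in one direction was 0.0165 for photosynthesis, 0.118 for the tapetum and pollen wall, 0.134 for the heat response and 0.0165 for floral organ identity. For changes in any direction 12 of the 17 lists passed with fry, the heat response not among them (adjusted p = 0.0797 with limma). Fry asks whether the members of a list change at all, while camera sets them against the other genes. With 2441 of 9428 genes past the threshold, a pass in any direction does not set a list apart. Adjusted over the list alone, the counts were 23 falls in photosynthesis, 10 rises in the tapetum and pollen wall, and 5 rises and 1 fall in floral organ identity.

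**Figure D1:**
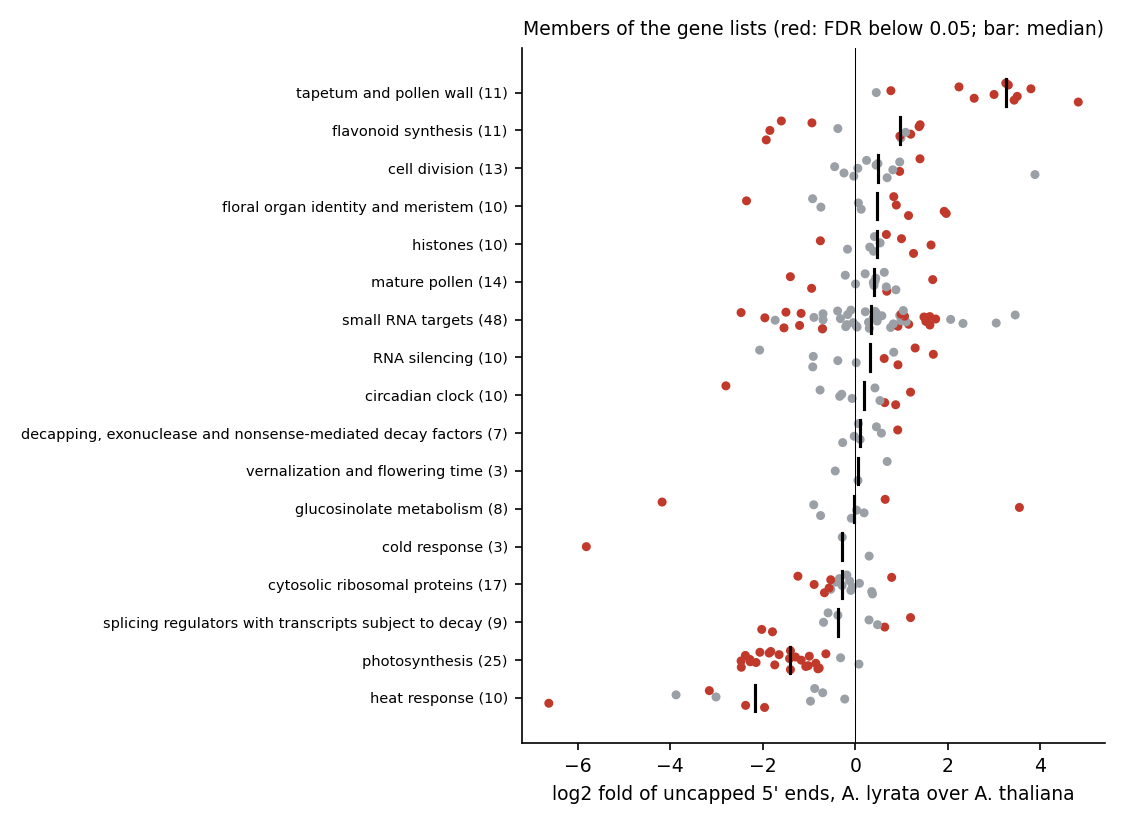
Log2 fold of uncapped 5' ends in A. lyrata over A. thaliana (horizontal axis) for each measured member of the 17 gene lists, with the number measured in parentheses; red points passed a false discovery rate of 0.05 and bars are list medians. The median was 3.25 for the tapetum and pollen wall and -1.40 for photosynthesis.

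The other 13 lists did not pass with camera. With fry in limma, 3 of them passed for a change on balance in 1 direction, cell division (adjusted p = 0.0165), the decay factors (0.0285) and the clock (0.0361). For changes in any direction 9 of them passed, which does not set them apart from other genes. Flavonoid synthesis moved both ways, with 4 rises and 4 falls among 11 measured (adjusted p = 0.231). TT4, the chalcone synthase, rose by 1.40 ± 0.14, FLS1, the flavonol synthase, by 1.38 ± 0.21 and F3H by 0.96 ± 0.19, whereas DFR, at the branch to anthocyanins, fell by 1.60 ± 0.35 on the log2 scale. Histones had 4 rises and 1 fall among 10 (adjusted p = 0.125), with HTB1 at 1.26 ± 0.35 and the histone H4 locus AT3G53730 at -0.76 ± 0.23. Of 10 clock transcripts, 3 rose and 1 fell (adjusted p = 0.441). LHY, a morning factor of the clock, rose by 0.87 ± 0.20, CCR1 by 1.19 ± 0.22 and GRP7 by 0.64 ± 0.20, and TOC1, an evening factor, fell by 2.80 ± 0.69 on the log2 scale. Of 10 RNA silencing transcripts 4 rose and 0 fell (adjusted p = 0.431), namely DCL3 by 1.69 ± 0.40, SGS3 by 1.29 ± 0.29, AGO2 by 0.92 ± 0.33 and AGO4 by 0.62 ± 0.22. Of 8 glucosinolate transcripts, 2 rose and 1 fell (adjusted p = 0.924), with AOP2 up by 3.55 ± 0.88, the myrosinase TGG1 up by 0.65 ± 0.15, and CYP79B2, which fell by 4.18 ± 0.85 on the log2 scale. The *A. thaliana* locus of AOP2 is annotated as a transcribed pseudogene and had only 12 and 9 tags there. CYP79B2 had only 9 and 12 tags in *A. lyrata*. Of 14 mature pollen transcripts, 2 rose and 2 fell (adjusted p = 0.287), with ACT12 at 1.67 ± 0.31 and the pectin methylesterase locus AT5G07430 at -1.40 ± 0.21. With distinct positions TT4 was at 0.57, DFR at -2.77, GRP7 at 1.27 and CYP79B2 at -3.14. With the highest position left out TOC1, GRP7, CYP79B2 and AOP2 were at -3.69, 1.61, -5.20 and 5.28. DFR was at -3.19 with tags of a single alignment and -0.89 with every alignment counted once.

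Of 17 cytosolic ribosomal protein transcripts, 1 rose and 5 fell (adjusted p = 0.231), with RPS13A at -1.24 ± 0.21 and RPL18 at -0.89 ± 0.21. Of 13 cell division transcripts, 2 rose, MCM3 by 1.40 ± 0.46 and MCM5 by 0.96 ± 0.37 (adjusted p of the list = 0.231). The list of 7 measured decay factors had an adjusted p of 0.431 with camera in limma. Of 9 splicing regulators 2 rose and 2 fell (adjusted p = 0.759), with SR30 at -1.79 ± 0.31. Only 3 transcripts each were measured for the cold response (adjusted p = 0.607) and for vernalization and flowering time (adjusted p = 0.759). COR15B, a cold-regulated protein, fell by 5.81 ± 1.44 on the log2 scale, with only 6 and 2 tags in *A. lyrata*. ERD10 at 0.30 ± 0.15 and KIN2 at -0.28 ± 0.18 did not pass, nor did FY, FCA and VRN1. The 48 measured small RNA targets had 9 rises and 7 falls (adjusted p = 0.148), with HAM3, COX5B, HAM2 and the laccase IRX12 up by 1.61, 1.74, 1.48 and 1.53 on the log2 scale. With distinct positions in place of tags, HAM2 stood at -0.03 and HAM3 at 0.35, and neither passed, while MCM3 was at 0.78 and COR15B at -3.54. HAM3 was at 0.86 without *A. thaliana* replicate 1 and 2.27 without replicate 2, and COR15B was at -6.58 without *A. lyrata* replicate 1 and -4.14 without replicate 2. HAM2 was at 0.81 and SR30 at -2.44 without *A. thaliana* replicate 1. With the highest position left out HAM3 and HAM2 were at 1.02 and 0.79.

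Adjusted over the list alone, the counts were 1 rise for cell division, 4 rises and 3 falls for RNA silencing, 12 rises and 9 falls for the small RNA targets, and 1 rise for vernalization and flowering time. In the other lists that did not pass they equalled the counts over all genes. The clock list had a median log2 fold of 0.18 and a mean of -0.06. The glucosinolate list had a median of -0.03 and a mean of -0.19, while camera gave it the upward direction. Of the list members named above, SGS3 at 1.08 and TGG1 at 0.45 did not pass without *A. thaliana* replicate 1, and DCL3 at 1.22 did not pass without *A. thaliana* replicate 2. AGO2, AGO4, MCM5, MCM3, GRP7, HTB1 and the histone H4 locus AT3G53730 each lost the call without more than 1 of the libraries, left out in turn. TGG1 stood at 0.10 with distinct positions and did not pass.

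The second comparison asked whether target transcripts carried a 5' end peak where a small RNA would direct cleavage. In *A. thaliana*, 9 of 16 pairs with a placed model had their highest position at the predicted site in both replicates, against a mean of 0.35 for random covered positions (permutation p = 1e-04, the smallest that the draws can give). HAM3, a GRAS-domain factor of the shoot meristem targeted by miR171, had 69.7% and 82.8% of its tags at the site, 284 of 407 and 782 of 944. Its site lies in the coding sequence of exon 1, at chromosome 4 position 58420 of TAIR10.1. TOE2, an AP2-type floral repressor targeted by miR172, had 41.7% and 54.2% at chromosome 5 position 24210900, in the coding sequence of exon 9. TAS1A, TAS1B, TAS1C and TAS2, non-coding precursors of trans-acting small RNAs, had 28.3% and 39.3%, 58.4% and 65.4%, 43.9% and 46.9%, and 35.7% and 44.0% at the miR173 site in replicates 1 and 2. The site of TAS2 lies at chromosome 2 position 16540000 and that of TAS1C at chromosome 2 position 16537899. TCP3, targeted by miR319, had 20.7% and 20.9% at its site. ETT, an auxin response factor targeted by the small RNAs of TAS3, had 12 of 80 and 15 of 105 tags there. AGO1, the slicer of the microRNA pathway, had only 4.13% and 2.42% at the miR168 site, with Wilson intervals of 2.89 to 5.87% and 1.54 to 3.80%, and that position was still its highest.

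The peak was absent from both replicates or present in 1 replicate for the other 7 pairs. TCP10 passed in replicate 2 only, with 24.0% against 7.16% in replicate 1. ARF2, a tasiRNA target, had 0 of 640 and 0 of 519 tags at the site, with upper Wilson limits of 0.597% and 0.735%. APS1 had 0 of 491 and 4 of 407 tags at its miR395 site, and ARF8 had 1.84% and 0.986% at its miR167 site. SPL3 had 0.794% and 6.40% at its miR156 site, and RPF3 did not pass for either of its 2 small RNAs.

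The sites of *A. lyrata* were not placed, so the species were compared by whether the highest position of a listed target was the same in both replicates. It was so for 33 of 84 targets in *A. thaliana* (39.3%, Wilson interval 29.5 to 49.98%) and for 19 of 43 in *A. lyrata* (44.2%, 30.4 to 58.9%). Transcripts of matched depth gave 9.38% and 8.08% (permutation p = 1e-04 in each species, the smallest that the draws can give). If these positions are the predicted sites, bases recorded as different from the model should rarely equal the *A. thaliana* reference base. They did so for 12 of 390 bases over 27 *A. thaliana* targets (3.08%) and for 20 of 244 bases over 11 *A. lyrata* targets (8.20%), against 24.6% and 24.3% at random offsets (permutation p = 1e-04 in each, the smallest that the draws can give). The *A. thaliana* value includes models that had been placed from the same bases, and the pairs had been looked at one by one before the test. Only targets with a penalty of at most 4.5 and at least 5 differing bases near the position entered it. ARF10, with 3 such bases in *A. lyrata*, did not enter there. All matching *A. thaliana* bases lay in PHO2 (5 of 10), SPL2 (3 of 9), SPL4 (2 of 14) and TCP3 (2 of 8). The pooled value therefore does not tie each position to its site, least of all that of PHO2. The targets named next were chosen after their values were seen. HAM1, HAM2 and HAM3, all targets of miR171, carried the most tags in *A. lyrata*, with CPM of the whole library of 194 and 134, 132 and 114, and 339 and 215 in replicates 1 and 2. AFB2, an auxin receptor targeted by miR393, had 13.5 and 13.3 CPM, and MYB33, a factor of anther development targeted by miR159, had 11.1 and 8.23. The auxin response factors ARF8 and ARF10 had 10.6 and 6.32, and 2.96 and 3.89 CPM. TCP2, AP2 and NAC100 had 5.36 and 7.15, 4.52 and 4.21, and 2.54 and 2.43 CPM. In *A. thaliana*, the highest positions of HAM1, ARF16, AFB3, ARF17 and NAC1 carried 57.8 and 85.8, 10.7 and 35.1, 19.8 and 22.2, 10.6 and 14.7, and 6.87 and 15.71 CPM.

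The share of a target's tags at its highest position was compared between the species for 11 targets. With limma 0 targets passed a false discovery rate of 0.05. The count at an unadjusted level of 0.05 was 1, HAM2, whose adjusted p was 0.157 with limma. HAM2 had 65.2 ± 4.32% in *A. thaliana* and 78.6 ± 0.307% in *A. lyrata* (SD, n = 2). HAM1 had 83.6 ± 0.322% and 88.3 ± 0.425%, and HAM3 had 76.3 ± 9.23% and 84.9 ± 2.45%. MYB33 had 63.1 ± 0.794% and 64.0 ± 4.11%, ARF10 had 26.7 ± 6.08% and 14.9 ± 0.694%, and TCP2 had 21.4 ± 7.87% and 37.0 ± 4.29%. These targets were taken because both species had a reproducible highest position, and the *A. lyrata* position was not tied to the site by its own sequence.

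**Figure D2:**
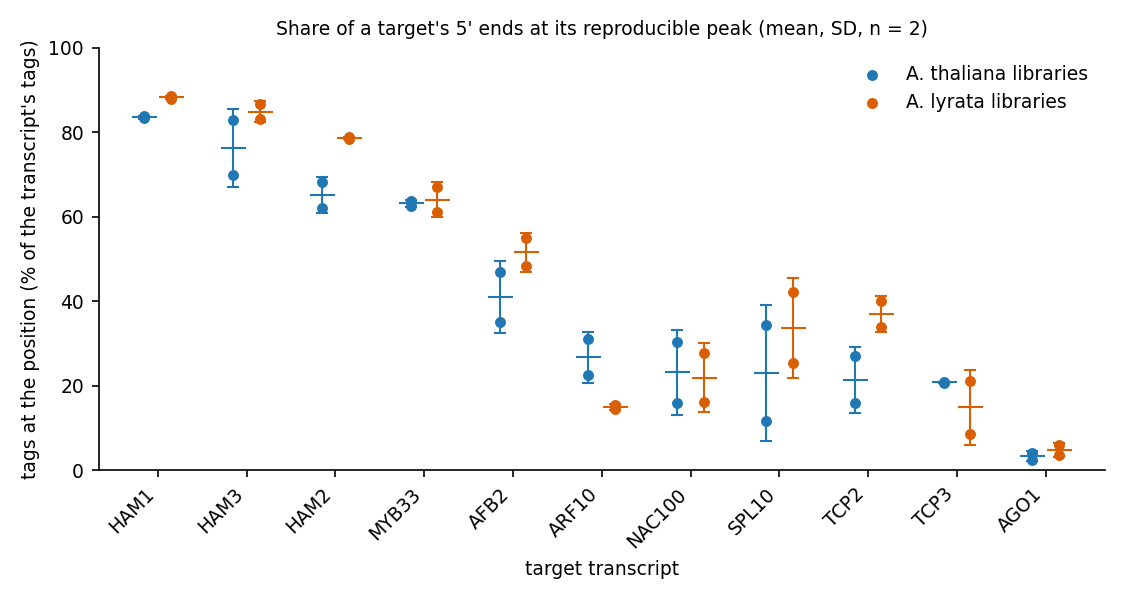
Percent of a target transcript's tags at its reproducible highest position (vertical axis) for 11 small RNA targets; points are libraries, horizontal marks are means and bars are SD (n = 2 per species). HAM1 had 83.6% in A. thaliana and 88.3% in A. lyrata, and AGO1 had 3.28% and 4.71%.

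Over all transcripts, listed targets included, the replicates shared few highest positions. Among 13419 *A. thaliana* transcripts with at least 20 tags in each replicate, the highest position was the same in 1019 (7.59%, Wilson interval 7.16 to 8.05%), against 0.599% for random covered positions. In *A. lyrata* it was the same in 616 of 14384 (4.28%, 3.96 to 4.63%), against 0.502%. Across transcripts, which are not independent replicates, the log2 tag totals of the replicates correlated with Pearson r = 0.91 and Spearman rho = 0.90 in *A. thaliana* and with r = 0.89 and rho = 0.90 in *A. lyrata*.

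Along placed *A. thaliana* transcripts the tags of a single alignment were spread unevenly. With each transcript divided into 10 equal parts, the first held 2.66% and 3.09% in replicates 1 and 2, the fourth 11.8% and 13.7%, and the fifth 10.35% and 11.05%. The eighth part held 15.4% and 14.3%, the ninth 16.1% and 14.1%, and the last 4.63% and 3.43%. The parts are those of the reference model, and 1333 of 2609 models in replicate 1 were placed at another offset than 0. Where the authors' model begins downstream of the reference start, the bases before it could hold no tags. Tags that begin close to a model's end could not align in full. The low first and last parts may therefore reflect the models in part. Counting each position once, or giving each transcript the same weight, the eighth part held the most, 15.1% and 14.6% as means of the replicates. The fourth part then held less than the fifth, 9.84% against 11.2% by position and 9.26% against 10.5% by transcript. Within coding sequences the codon frames were near even, with frame 0 at 34.6% and 34.7%. Positions 27 to 30 nt before the first base of the next exon were covered 1.22 times (95% bootstrap interval 1.18 to 1.26) and 1.25 times (1.21 to 1.29) as often as the flanks. Positions 16 to 17 nt before the stop codon were covered 1.198 times (1.13 to 1.27) and 1.21 times (1.14 to 1.29) as often. Both windows were chosen after the profiles had been seen.

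**Figure D3:**
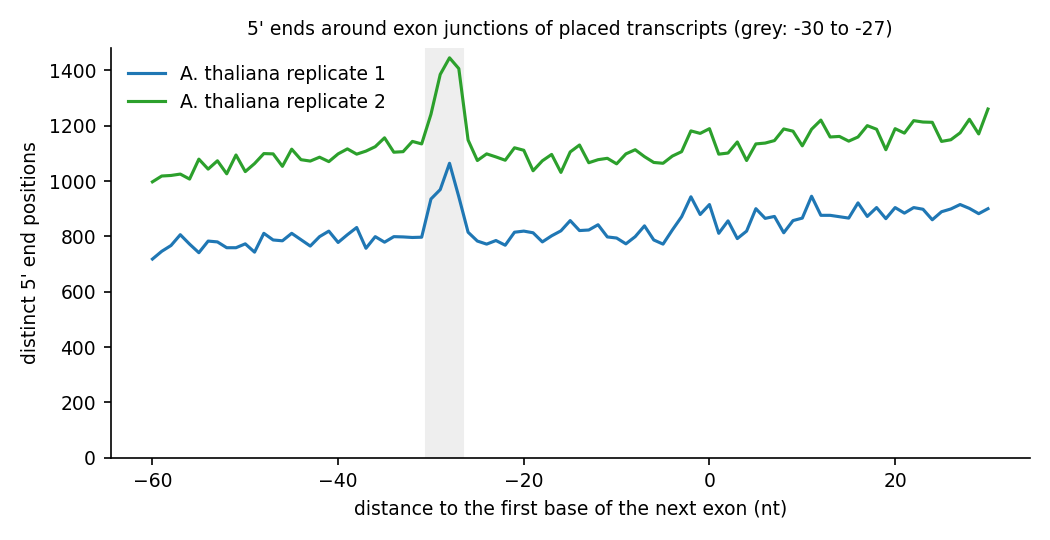
Number of distinct 5' end positions (vertical axis) by distance to the first base of the next exon in nt (horizontal axis), summed over placed A. thaliana transcripts, 1 line per replicate. The grey band marks 27 to 30 nt before the junction, where coverage was 1.22 and 1.25 times that of the flanks.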

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

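The tests of recurrence against a Poisson draw, of distinct positions and of covered extent were chosen after the results they bear on had been seen. Tags outside the comparisons took large shares of every library. In *A. lyrata*, 1 position of an unpaired transcript model, whose identity was not analysed here, took 12.4% of the tags of replicate 1 and 6.67% of replicate 2. In *A. thaliana*, position 3 took 5.66% and 9.59% of the tags in each of 2 ribosomal RNA models with equal counts there, in a count that divides tags among their alignments. Ribosomal RNA took 38.6% and 48.7%, organelle transcripts 20.5% and 17.2%, and small nucleolar RNA 7.34% and 6.28% of the *A. thaliana* tags, in data the comparisons do not use.

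Photosynthesis transcripts were lower and tapetum transcripts higher in *A. lyrata* at the preset correlation, but neither list passed with an estimated correlation (adjusted p 0.355 and 0.608 with camera in limma), which was not run for the 2 settings below. Copies of a few amplified fragments as the whole cause are argued against by distinct positions, where the adjusted p with camera in limma was 5.69e-09 for photosynthesis, with the median at -0.76 from -1.40, and 1.39e-07 for the tapetum list, at 3.07 from 3.25. Transcript models of different extent as the whole cause are argued against by pairs with near-equal covered extent, where the adjusted p was 1.68e-22 and 5.02e-09. With the trend over GC content and transcript length removed, the list medians were -1.49 and 3.03 (log2), outside the central 95% of 10000 random lists, -0.49 to 0.48 and -0.78 to 0.72. Both traits were those of the *A. thaliana* reference transcripts, so differences of the *A. lyrata* transcripts from them were not removed. Copies as a part of the photosynthesis change, a different mix of floral stages, the cold period of *A. lyrata* and the time of harvest stay open, the last 3 untested because they go with the species. Whether transcript level or decay differs cannot be told either, since the libraries hold uncapped RNA only.

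Most positions were seen in only 1 replicate, and positions with 5 to 9 tags recurred at most 0.293 times as often as a Poisson draw at the other library's depth. That draw takes tags as independent molecules and separate samples as alike, so too few molecules per position stay open. Amplification copies of single fragments stay open too: positions with 10 to 19 tags that did not recur had a covered neighbour 1 nt away 1.15 to 1.49 times as often as positions with 1 tag in the 4 libraries. The largest, 1.49, lies between the bounds set before the test, at or under which copies would account for the pattern and above which they would not. No biological explanation was tested.

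Positions 27 to 30 nt before exon junctions were covered more often than the flanks. Base preference at the 5' end accounts for at most 1.45% of the rise, as computed from the 6 bases around each position. Wrong placement of models is argued against by models placed at another offset than 0, where the lower bound of the rise was 1.15. No biological explanation was tested.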

How the results depend on the processing

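With 2 libraries per species, leaving 1 out keeps a fit in which the lone library is assumed to vary like the other species. On simulated counts at this depth, 22.2% of 2-fold changes were recovered. The settings distinct positions, every alignment counted once, near-equal covered extent, limma-trend and a posterior of 0.9 were chosen after the data had been seen. The cause of the changes below was not tested. For abundance, the other settings gave 2432 to 3174 genes against 2441. With pairs of near-equal covered extent, where 6491 genes were tested, 1573 passed, 669 higher and 904 lower, and with distinct positions 1561 were higher. Leaving out each library gave 1257 to 2663 genes, 419 to 1240 higher and 838 to 1423 lower. The 84 named genes had 1046 values over the settings, of which 973 kept direction and side of the threshold, 46 lost the call, 15 gained it and 12 changed sign. The changed signs were AT5G13380 at -5.51 with tags of a single alignment, AT5G13380 at -3.80, ERD10 at -0.18, KIN2 at 0.047 and HAM2 at -0.026 with distinct positions, and VRN1 at -0.017 with every alignment counted and -0.012 with near-equal extent. Without single libraries the log2 fold in abundance of KIN2 AT5G15970 ranged from -0.63 to 0.039, that in abundance of DCP2 AT5G13570 from -0.043 to 1.19 and that in abundance of VRN1 AT3G18990 from -0.12 to 0.24.

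For the lists, 0 passed with an estimated correlation, with adjusted p of 0.355 for photosynthesis, 0.608 for the tapetum and pollen wall, 0.608 for the heat response and 0.608 for floral organ identity. Leaving out each library gave 2 to 4 lists, with adjusted p of 0.0357 to 0.113 for floral organ identity and 0.0023 to 0.194 for the heat response. Floral organ identity had 0.299 with distinct positions. Lists that did not pass changed direction for the clock (adjusted p 0.648 with near-equal extent) and for glucosinolates (0.679 with distinct positions, 0.930 with near-equal extent and 0.828 without *A. thaliana* replicate 1). Glucosinolates kept the upward direction without each of the other 3 libraries (0.286 to 0.834).

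Peaks at placed sites were found for 9 of 16 pairs in the main setting and 8 to 11 of 16 in most others. They were found for 6 of 12 pairs with a penalty of at most 3.5 and for 10 of 17 with a posterior of 0.9. No target passed in the difference of shares in any of 77 values. With the exact position the log2 odds differences of SPL10, TCP3, MYB33 and NAC100 were -0.11, 0.25, -0.39 and 0.14, and without single libraries TCP3 ranged from -1.49 to 0.0102, MYB33 from -0.12 to 0.24 and NAC100 from -0.69 to 0.53. The same highest position was found in 10.2% and 5.35% of transcripts with at least 50 tags, and in 8.70% and 5.63% within 1 nt, in *A. thaliana* and *A. lyrata*. Counting each position once, or giving each transcript the same weight, gave 12.5% and 12.4% in the ninth part, 4.95% and 5.85% in the last part and 33.98% and 34.4% in frame 0.

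With the replicate number as a block, 2505 genes and 4 lists passed, glucosinolates changed direction (adjusted p 0.935) and so did the share of MYB33 (-0.00307). Deviations of libraries with the same number correlated at 0.0173, so the numbers were not read as pairing the samples. Offsets for transcript length, the count-based Wald test and the site settings for *A. lyrata* were not run.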

Other observations

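The thresholds and the test in this part were chosen after the data had been seen, and no others were tried. Some transcripts outside the list of small RNA targets had at least 30% of their single-alignment tags at 1 position, the same within 1 nt in both replicates. Among 6268 gene pairs with at least 20 such tags in every library, 37 had such a position in *A. thaliana* and 33 in *A. lyrata*. In 10 pairs it was present in both species, where 0.195 were expected from independent sets (two-sided Fisher's exact test p = 1.15e-15 across genes, which are not independent replicates). ADF7, an actin-depolymerising factor of pollen, had 84.5% and 74.9% at position 81 of the *A. thaliana* model and 72.6% and 67.6% at position 79 of the *A. lyrata* model. AT3G17380 had 94.7% and 91.2% at position 59 in *A. thaliana* and 100% in both *A. lyrata* libraries at position 59. AT5G65860 had 90.5% and 93.3% at position 146 and 90.9% and 93.1% at position 118. VPS9A, a guanine nucleotide exchange factor of endosomes, had 53.9% and 47.5% at position 95 and 31.1% and 32.0% at position 93. UMAMIT31, GLP10, AT3G13175, AT4G15940, AT4G18580 and AT4G36850 made up the rest. Whether the positions of a pair are the same base was not tested, since the models begin at different bases.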
